A study of Mus musculus with 28 samples.

How the data were processed

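RNA of RAW264.7 cells was measured on 28 spotted arrays with cRNA in Cy5 and Cy3, per the labels. 26 arrays set treated against time-matched untreated cells and 2 untreated against untreated. By title, the 2 arrays exchanged dyes in 13 of 14 extracts. RNA was extracted with TriPure, arrays were scanned with an Agilent Scanner G2505A, and spots were quantified with Agilent Extraction Software, release A, version 6.1.1, per the labels. Per the file headers, the scanner files of the authors hold spot and local background signals as intensity in scanner counts, background-subtracted and dye-normalized signals as intensity, and log ratios of red over green on a log10 scale. The deposited value table holds log2 ratios of treated over untreated, normalized by the authors in a way not given in the sources used here. Its unit was checked on the values. Every column had a median of 0, between 4.97% and 36.0% of a column's values were exactly 0, and in the 15 of 26 treated columns that correlated above 0.7 with their own arrays the slope on the log2 ratios of the scanner files lay between 0.521 and 1.07. Only 19 of the 26 treated columns had their highest correlation with their own treatment and time (own correlations -0.281 to 0.980), and in the others the direction, scale or sample could not be established, so the table served as an alternative only.

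Mean spot signals were corrected with normexp and an offset of 50 and normalized within each array by loess in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the data.table package), where control spots and the 3415 spots that the scanner software marked as outliers (0.770%) had weight 0. Titles of the arrays name the Cy3 sample before the Cy5 sample, and this order matched the dye labels on 25 of 28 arrays. On 1 KDO array at 120 min and both arrays of the 3 ligands at 120 min title and dye label conflicted, and the title order was used. With the title order these arrays correlated with the 60 min extract of their treatment at r = 0.567 to r = 0.629 over probes, and with the dye labels at the same values with a negative sign. A dye effect per probe, estimated from the 13 extracts with both dye orders, was subtracted, and the arrays of an extract were averaged to 14 extract-level samples. Probes well above background by the scanner's own mark in at least 1 channel on every array of at least 1 extract were kept, and spots of the same probe were averaged. Of 16281 features, 441 were controls and 15840 held 15822 distinct probes, of which 15443 met the filter and 15215 had a value in every extract, for 7047 named genes. The depth of an array is its signal over background, and between 78.4% and 96.3% of probe features per channel stood well above it.

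Each treatment and time had 1 coefficient (12 in all) in limma's lmFit and eBayes, and the untreated pair had none, since its expected log ratio is 0. The 2 residual degrees of freedom came from the 2 KDO extracts at 120 min and the untreated pair, with a prior of 7.65 degrees of freedom and a prior SD of 0.125. The 11 combinations with a lone extract were assumed to vary like the replicated samples, and ratios against untreated RNA leave out part of the control's spread, so that p-values are too small if lone extracts carry components of their own. Tests were two-sided, adjusted by Benjamini-Hochberg over 15215 probes within each of 12 comparisons. The comparisons were the 6 treatments against untreated cells, IFN-β and 8-Br added to KDO, 8-Br added to KDO and IFN-β, the departures of KDO with 8-Br and of KDO with IFN-β from the sum of the single treatments, and 120 against 60 min over all treatments. Each comparison averages both times, and single times were tested in the same fit. Slide was not a term because each of the 17 slides held arrays of 1 group only. A gene with several probes is given by its brightest probe, and probes more than 1 log2 unit apart are named. A value whose brighter channel was saturated on all arrays is given as a bound, unless the other side was saturated too.

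Symbols came from the files' gene names and a reference of synonyms. Of the probe features 9964 received a symbol (7231 distinct) and 5876 did not, 4226 of them with a name. No genome coordinates were used, and probes were not realigned, so that close paralogs such as Birc2 and Birc3 or Hspa1a and Hspa1b could share signal. Before the data were examined, 15 gene lists (433 genes, 368 on the array), the comparisons, the tests and all but 2 alternatives were fixed. The lists were inflammatory cytokines and chemokines, NF-κB subunits, inhibitors and feedback, immediate early genes, interferon-stimulated genes, cAMP and CREB target genes, negative regulators of TLR and cytokine signalling, alternative activation, MHC and antigen presentation, cell cycle and DNA replication, sterol synthesis and efflux, stress and unfolded protein response, macrophage surface and lineage genes, proteases, matrix and adhesion, control genes and markers of other cell types. Lists for TLR4 and cAMP targets were included because Kdo2-lipid A, a ligand of TLR4, and 8-bromo-cAMP are commonly abbreviated as KDO and 8-Br in work with this cell line, which the labels do not state. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 180 tests. The version with an estimated correlation rests on the fit's 2 residual degrees of freedom, so small p-values were hardly within its reach. The named genes were, in the 3 single treatments and the 3 comparisons of an added ligand, the 8 largest rises and 6 largest falls past the threshold with 1 sign at both times and on every array, and up to 3 members of each list by size. For departures and time they were the 5 largest in each direction. This left 151 genes after leaving out those withheld for evaluation, which are not reported here. The 151 genes are also quoted in comparisons other than those that named them. Il1a, Il1b, Il6, Il10 and Tnf are list members.

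The fit was tested on simulated data with 15215 probes, where all extracts had independent noise of the same spread per probe. The simulation therefore cannot show the share of false calls if lone extracts carry components of their own. With variances drawn from the fitted prior, 70.1%, 100% and 100% of probes changed by 0.5, 1 and 2 log2 units were called for KDO, with 4.76% of calls false. For 8-Br added to KDO the shares were 15.7%, 96.3% and 100% (3.75% false), and for the departure of KDO and 8-Br 4.48%, 79.9% and 100% (3.92% false). A list of 40 probes shifted by 0.5 in IFN-β alone had 0 probes called singly and a camera p of 4.63e-72 in this simulation, against 0.613 for a random list. The simulation was revised after a first version, which drew from already shrunken variances, gave more false calls. With such variances and a heavy tail 8.29% of the KDO calls were false. Alternatives were the scanner software's processed signals, offset 0, median centring, Aquantile, all probes, probes well above background everywhere, the deposited value table, both times as replicates, the dye labels, leaving out arrays or extracts, no dye effect, random blocks for extract or slide, a 2-fold limit and the estimated correlation. A fit without the 8-Br 60 min and IFN-β 120 min extracts and a fit of the value table with each column as a sample were chosen after seeing the data. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.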

Results

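RNA abundance was measured in RAW264.7 cells, an established mouse cell line that resembles macrophages, with 28 spotted oligonucleotide arrays of 15822 distinct probes. Each array outside the untreated pair carried RNA of treated and of time-matched untreated cells in different dyes. The cells received KDO at 100 ng/ml, the type I interferon IFN-β at 300 pM or 8-Br at 100 μM, or KDO with IFN-β, with 8-Br or with both, for 60 or 120 min. The labels do not spell out KDO or 8-Br. KDO at 120 min was represented by 2 RNA extracts and each of the other 11 combinations of treatment and time by 1, and each extract was hybridised on 2 arrays. The untreated pair, 2 of the 28 arrays, set untreated cells against untreated cells at 60 min. The labels state only duplicate experiments, and nothing says that extracts came from separate cultures. The p-values therefore measure only the spread between these samples, taken from the 2 KDO extracts at 120 min and the untreated pair. Spread within the other 11 combinations was not measured, and their SE and p-values assume that they vary alike. Between 78.4% and 96.3% of the probe features stood well above background per channel, and the number of arrays limits the precision. Over probes, which are not independent replicates, the paired arrays of a treated extract correlated at r = 0.372 to r = 0.944, the lowest with all 3 ligands at 120 min. In the untreated pair the log2 ratios had an SD of 0.11, 1 of 15215 tested probes lay beyond 2-fold, and Tnf stood at -0.018. Values are log2 ratios of treated over untreated, as the mean of 60 and 120 min ± SE, unless a time is given. Counts refer to probes past an adjusted p of 0.05 in limma.

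Which transcripts KDO alone changed was asked with n = 3 extracts on 6 arrays. Tnf, which encodes the cytokine tumour necrosis factor, rose by 3.42 ± 0.10 (10.7-fold, adjusted p = 1.94e-08). Il1b, which encodes interleukin-1β, rose by 3.70 ± 0.09 (adjusted p = 6.15e-09). The early-response transcription factor genes Egr1 and Egr2 rose by 3.72 ± 0.13 and 3.57 ± 0.08, and Dusp2, which encodes a phosphatase of MAP kinases, rose by 3.44 ± 0.07. Cxcl2, which encodes a chemokine for neutrophils, rose at least 32.2-fold, a bound because its probe was saturated in the treated channel of 6 of 6 arrays. All of these were higher on 6 of 6 arrays. Tnfaip3, which encodes the ubiquitin-editing enzyme A20, rose by 2.34 ± 0.09 and Zfp36, which encodes an mRNA-destabilising protein, by 2.69 ± 0.08. Among the falls were Txnip, which encodes an inhibitor of thioredoxin, at -1.30 ± 0.09 (adjusted p = 1.31e-05), Rgs2, a regulator of G-protein signalling, at -1.79 ± 0.10, the lipopolysaccharide receptor gene Tlr4 at -0.67 ± 0.07 and the growth factor receptor gene Csf1r at -0.38 ± 0.07.

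Of the 27 measured inflammatory cytokine and chemokine genes, 18 rose, 0 fell and 9 did not pass the threshold (19 and 0 adjusted over the list alone), with Ccl22 (0.97) and Il10 (0.97) among the smaller rises and Il6 at 0.042 not past it. Camera, which compares a list with all other probes, gave this list adjusted p = 1.72e-24 with the preset correlation and adjusted p = 0.210 with an estimated correlation. 21 of 25 genes of NF-κB subunits, inhibitors and feedback rose and 0 fell (22 and 0 adjusted over the list alone), including Nfkbiz at 2.85, Ier3 at 2.70 and Traf1 at 2.43 (adjusted p = 3.37e-31 with the preset correlation and adjusted p = 0.163 with an estimated correlation). 25 of 29 immediate early genes rose and 0 fell (26 and 1 adjusted over the list alone), Btg2 at 3.17 being the next largest after the Egr genes and Dusp2 (adjusted p = 4.16e-31 with the preset correlation and adjusted p = 0.163 with an estimated correlation). Among the other signalling lists, 18 rose and 3 fell among 34 cAMP and CREB target genes (18 and 3 adjusted over the list alone), including Pde4b at 2.58 and Gadd45a at 2.17. For inhibitors of signalling, 11 rose and 2 fell among 27 negative regulators of TLR and cytokine signalling (11 and 2 adjusted over the list alone). In the interferon-stimulated list 7 of 48 rose and 4 fell (10 and 5 adjusted over the list alone), Cxcl10 reaching 1.83. Of the sterol synthesis and efflux genes 6 of 19 rose and 0 fell (8 and 0 adjusted over the list alone). 4 of 19 stress and unfolded protein response genes rose and 1 fell (4 and 1 adjusted over the list alone), with Herpud1 at 1.16. 6 of 28 protease, matrix and adhesion genes rose and 1 fell (6 and 1 adjusted over the list alone), with Plaur at 1.39. 5 of 18 markers of alternative activation rose and 1 fell (8 and 1 adjusted over the list alone). In addition, 2 rose and 4 fell among 30 macrophage surface and lineage genes (6 and 4 adjusted over the list alone), Tlr2 at 0.77 being one of those that rose. Few members moved elsewhere, as 1 rose and 1 fell among 22 MHC and antigen presentation genes (0 and 0 adjusted over the list alone). Likewise, 1 rose and 3 fell among 36 cell cycle and DNA replication genes (2 and 3 adjusted over the list alone) and 0 rose and 1 fell among 21 markers of other cell types (0 and 0 adjusted over the list alone). Beside these, 0 of the 14 control genes passed (limma, 2 at an unadjusted p under 0.05, 0 adjusted over the list alone), at a median of 0.11.

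In all, 960 were higher and 906 lower with KDO, of which 142 changed at least 2-fold. The total of 1866 became 3976 without the first KDO 120 min extract, 1160 without the untreated pair, 1144 without the 3 arrays whose labels conflict, 194 (31 lower) with both times taken as replicates and 0 with the dye labels in place of the title order (limma, 728 at an unadjusted p under 0.05). Higher and lower calls numbered 370 and 227 with offset 0 and 1387 and 589 with median centring. Second probes differed from the ones given for Cxcl2 (-0.0061), Lynx1 (0.088 against 3.14), Nfkbiz (4.34), Il1rn (-0.061 against 1.08) and Herpud1 (0.077).

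What IFN-β alone changed was asked with n = 2 extracts on 4 arrays, 1 extract per time. Interferon-stimulated genes gave the largest rises. Iigp1, which encodes an immunity-related GTPase, rose by 4.69 ± 0.09 (25.9-fold, adjusted p = 1.83e-09, higher on 4 of 4 arrays). Socs1, which encodes an inhibitor of cytokine receptor signalling, rose by 4.52 ± 0.10. The guanylate-binding protein gene Gbp3 rose by 3.86 ± 0.08, the antiviral gene Ifit2 by 3.97 ± 0.09, the chemokine gene Cxcl11 by 3.90 ± 0.10 and the transcription factor gene Irf1 by 3.90 ± 0.08, each on 4 of 4 arrays. Myc, a transcription factor gene of proliferating cells, was lower at -1.77 ± 0.09 (adjusted p = 1.16e-06, lower on 4 of 4 arrays), as were the repressor gene Bcl6 at -1.06 ± 0.09 and the growth factor gene Pdgfb at -0.99 ± 0.08. Of the 48 measured interferon-stimulated genes, 42 rose, 1 fell and 5 did not pass the threshold (43 and 1 adjusted over the list alone). Their median was 1.38 at 60 min and 2.25 at 120 min, and camera gave adjusted p = 4.39e-50 with the preset correlation and adjusted p = 0.184 with an estimated correlation. Outside that list, 9 rose and 0 fell among 27 inflammatory cytokine and chemokine genes (9 and 1 adjusted over the list alone), including Ccl12 at 2.03. Similarly, 10 rose and 3 fell among 25 genes of NF-κB subunits, inhibitors and feedback (12 and 3 adjusted over the list alone), including Map3k8, a kinase gene upstream of ERK, at 2.15 and Cd40 at 1.83. The chemokine gene Ccl4 rose by 2.54 with its treated channel saturated on 3 of 4 arrays.

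Falls after IFN-β came mainly from the 120 min extract. Of the 36 measured cell cycle and DNA replication genes, 2 rose, 19 fell and 15 did not pass the threshold (3 and 20 adjusted over the list alone). However, Rrm2, which encodes a ribonucleotide reductase subunit, stood at 0.16 at 60 min and -1.81 at 120 min, and Kif23 at -0.045 at 60 min and -1.91 at 120 min. 1 of 19 stress and unfolded protein response genes rose and 11 fell (1 and 12 adjusted over the list alone), with Txnrd1 at 0.13 at 60 min and -1.71 at 120 min. In the control list 0 of 14 rose and 5 fell (0 and 6 adjusted over the list alone), Tbp standing at 0.039 at 60 min and -1.20 at 120 min. The control median was -0.28 in the 120 min extract and -0.16 over both times. With IFN-β at 60 min alone, 37 rose and 0 fell of the interferon-stimulated genes, 7 rose and 1 fell of the inflammatory genes and 3 rose and 0 fell of the NF-κB genes. In the same extract 1 rose and 0 fell of the cell cycle genes, 0 rose and 1 fell of the stress genes and 0 of 14 control genes passed (limma, 0 at an unadjusted p under 0.05). Over all probes 1408 were higher and 2074 lower, and 184 changed at least 2-fold. These 3482 calls became 263 (62 lower) without the 8-Br 60 min and IFN-β 120 min extracts, 123 (5 lower) with both times taken as replicates and 629 with the dye labels in place of the title order. The split was 824 and 2381 with median centring.

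For 8-Br alone (n = 2 extracts on 4 arrays) the largest rise was that of Areg, which encodes the growth factor amphiregulin, at 5.03 ± 0.09 (32.7-fold, adjusted p = 2.76e-09, higher on 4 of 4 arrays). The orphan nuclear receptor genes Nr4a1 and Nr4a2, known targets of cAMP signalling, rose by 3.84 ± 0.08 and 4.33 ± 0.08, each on 4 of 4 arrays. Ddit4, which encodes an inhibitor of mTORC1, rose by 4.05 ± 0.09, Fosb by 3.41 ± 0.12 and Vegfa, which encodes an angiogenic factor, by 3.37 ± 0.08, each on 4 of 4 arrays. Il1b rose by 3.17 ± 0.10 and Cxcl2 by 4.26 ± 0.10, although a second Cxcl2 probe stood at 0.098. Tnf went the other way at -2.09 ± 0.12 (adjusted p = 2.48e-06, lower on 4 of 4 arrays), with -2.50 at 60 min and -1.68 at 120 min. 20 of 29 immediate early genes rose and 3 fell (21 and 3 adjusted over the list alone), including Btg2 at 3.48 and Dusp1 at 3.38 (adjusted p = 7.74e-14 with the preset correlation and adjusted p = 0.165 with an estimated correlation). 20 of 34 cAMP and CREB target genes rose and 4 fell (20 and 4 adjusted over the list alone), at a list median of 0.28 at 60 min and 0.81 at 120 min (adjusted p = 2.31e-13 with the preset correlation and adjusted p = 0.165 with an estimated correlation). The inflammatory genes were divided, since 7 of 27 rose and 6 fell (8 and 6 adjusted over the list alone). 5 of 18 markers of alternative activation rose and 0 fell (5 and 0 adjusted over the list alone), with Klf4 at 2.17 and Tgm2 at 2.01. Abca1, which encodes a cholesterol exporter, stood at -0.49 at 60 min and 3.02 at 120 min.

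Falls after 8-Br came mainly from the 60 min extract. Txnip stood at -3.72 at 60 min and -1.35 at 120 min, the actin-linker gene Msn at -3.18 at 60 min and -0.60 at 120 min, and the lipid receptor gene Trem2 at -3.39 at 60 min and -0.29 at 120 min. Of the 30 measured macrophage surface and lineage genes, 3 rose, 14 fell and 13 did not pass the threshold (3 and 15 adjusted over the list alone). Moreover, 3 rose and 17 fell among 36 cell cycle and DNA replication genes (3 and 17 adjusted over the list alone), and 4 rose and 16 fell among 48 interferon-stimulated genes (4 and 17 adjusted over the list alone). In the control list 0 of 14 rose and 6 fell (0 and 6 adjusted over the list alone), at a median of -0.41 in the 60 min extract and -0.19 over both times. With 8-Br at 120 min alone, 1 rose and 1 fell of the macrophage genes, 1 rose and 1 fell of the cell cycle genes, 0 rose and 3 fell of the interferon-stimulated genes and 0 of 14 control genes passed (limma, 1 at an unadjusted p under 0.05). At that time 20 rose and 3 fell of the immediate early genes, 21 rose and 3 fell of the cAMP and CREB targets, 6 rose and 4 fell of the inflammatory genes and 5 rose and 0 fell of the markers of alternative activation. Second probes of Msn (-0.092), Serinc3 (-0.035 against -1.92) and Swap70 (0.15 against -1.86) did not share the fall. In all 1400 were higher and 2272 lower with 8-Br, 428 of them at least 2-fold. The total of 3672 was 774 (272 lower) without the 8-Br 60 min and IFN-β 120 min extracts, 152 (47 lower) with both times taken as replicates and 1424 (1086 lower) with the dye labels in place of the title order.

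Adding IFN-β to KDO was compared with KDO alone to find what the interferon contributed in the presence of KDO (5 extracts on 10 arrays). Cxcl9, which encodes a T-cell chemokine, was higher by 4.08 ± 0.13 (adjusted p = 3.79e-08) and stood at 4.14 ± 0.09 against untreated cells, compared with 0.057 with KDO and 1.37 with IFN-β. Il6, which encodes interleukin-6, was higher by 3.10 ± 0.11 (adjusted p = 7.71e-08), at 3.14 ± 0.08 against untreated cells. Gbp2b, Ifit2 and Iigp1 were higher by 5.22 ± 0.11, 4.64 ± 0.12 and 4.18 ± 0.12, and Atf3, a stress-induced repressor gene, by 2.46 ± 0.11. Lower than with KDO alone were Myc at -1.47 ± 0.12, Pdgfb at -1.31 ± 0.10, the DNA damage gene Gadd45a at -1.30 ± 0.12 and the granulocyte growth factor gene Csf3 at -1.14 ± 0.14, whose second probe stood at 0.38. Tnf did not pass (-0.26, adjusted p = 0.359). Ccl4 was saturated on 5 of 6 arrays with KDO and 4 of 4 arrays of the combination, so its difference is not determined. Of the 48 measured interferon-stimulated genes, 42 were higher, 0 were lower and 6 did not pass the threshold (45 and 0 adjusted over the list alone), at a median of 2.09 (adjusted p = 5.58e-66 with the preset correlation and adjusted p = 0.179 with an estimated correlation). For the inflammatory genes, 9 of 27 were higher and 3 lower (10 and 5 adjusted over the list alone). The control median was -0.12, and 0 of the 14 control genes passed (limma, 4 at an unadjusted p under 0.05, 0 adjusted over the list alone). Against untreated cells, 46 rose and 0 fell among 48 interferon-stimulated genes (46 and 0 adjusted over the list alone) and 21 rose and 0 fell among 27 inflammatory cytokine and chemokine genes (21 and 0 adjusted over the list alone). Of the MHC and antigen presentation genes 5 of 22 rose and 0 fell (10 and 0 adjusted over the list alone).

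The difference between the combination and the sum of KDO and IFN-β alone was tested on the log2 scale. Cxcl9 exceeded the sum by 2.71 ± 0.16 (adjusted p = 0.000212) and Il6 by 1.99 ± 0.13 (adjusted p = 0.000274). The kinase gene Pim1 (-2.19 ± 0.14) fell short of it. Cxcl10 and Ccl4 were saturated on 4 of 4 arrays of the combination, so their departures are not determined. In the interferon-stimulated list 1 of 48 were higher and 1 lower (6 and 4 adjusted over the list alone) than the sum, at a median of 0.22, beside a control median of 0.21. At 60 min 1 was higher and 0 lower at a median of 0.21 (control median 0.088), and at 120 min 1 was higher and 4 lower at a median of 0.15 (control median 0.42). Without the IFN-β 120 min extract 9 were higher and 1 lower at a median of 0.43 (control median -0.067), where means of both times are set against IFN-β at 60 min alone. Camera turned the direction of both lists with median centring. The departure passed for 23 higher and 29 lower probes, with 8 and 1 at 60 min and 178 and 147 at 120 min. The 52 calls became 889 (350 lower) without the first KDO 120 min extract, 498 (158 lower) without the second, 23 without the untreated pair, 16 without the 3 arrays whose labels conflict, 87 without the KDO 120 min array with another series number, 2 (all higher) with both times taken as replicates and 0 with the dye labels in place of the title order (limma, 562 at an unadjusted p under 0.05). The higher and lower departures numbered 0 with the scanner software's processed signals (limma, 1274 at an unadjusted p under 0.05), 0 with offset 0 (limma, 1259 at an unadjusted p under 0.05) and 16 and 35 with median centring. IFN-β added to KDO gave 555 higher and 415 lower (177 at least 2-fold). The combination against untreated cells gave 956 higher and 700 lower (278 at least 2-fold). The 970 calls of the former became 3834 without the first KDO 120 min extract, 2153 without the second, 509 (142 lower) without the untreated pair, 477 (133 lower) without the 3 arrays whose labels conflict, 71 (all higher) with both times taken as replicates and 127 (all higher) with the dye labels in place of the title order. Higher and lower, they numbered 199 and 15 with the scanner software's processed signals, 229 and 36 with offset 0 and 789 and 2345 with median centring. The 1656 calls of the latter became 3524 without the first KDO 120 min extract, 3527 without the second, 1067 without the untreated pair, 1067 without the 3 arrays whose labels conflict, 318 (43 lower) with both times taken as replicates and 293 (33 lower) with the dye labels in place of the title order. In higher and lower, these were 545 and 213 with the scanner software's processed signals, 586 and 248 with offset 0 and 728 and 2082 with median centring.

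Adding 8-Br to KDO was compared with KDO alone in the same way (5 extracts on 10 arrays). Il10, which encodes an anti-inflammatory cytokine, was higher by 2.09 ± 0.11 (4.26-fold, adjusted p = 2.83e-06) and Il6 by 2.0 ± 0.11 (adjusted p = 3.30e-06). Tnf was lower at -1.79 ± 0.16 (adjusted p = 0.000124). Tnf still stood above untreated cells with the combination, at 1.63 ± 0.12. Nr4a2, Ddit4, Areg and Vegfa were higher by 4.03 ± 0.11, 3.95 ± 0.12, 3.83 ± 0.12 and 3.24 ± 0.11. Procr, which encodes the protein C receptor, and Timp1, which encodes a metalloproteinase inhibitor, were higher by 2.89 ± 0.11 and 2.85 ± 0.11, and Abca1 by 2.06 ± 0.10. Csf3 was higher by 2.03 ± 0.14, with a second probe at 0.34. Lower were Egr2 at -2.24 ± 0.12, Myc at -2.31 ± 0.12, the polo-like kinase gene Plk2 at -2.56 ± 0.11, Rgs16 at -2.70 ± 0.14, Map3k8 at -1.26 ± 0.12 and Cxcl10 at -1.14 ± 0.13. Of the 34 measured cAMP and CREB target genes, 20 were higher, 3 were lower and 11 did not pass the threshold (23 and 4 adjusted over the list alone), at a median of 0.76 (adjusted p = 3.30e-18 with the preset correlation and adjusted p = 0.163 with an estimated correlation). 5 of 18 markers of alternative activation were higher and 0 were lower (8 and 0 adjusted over the list alone). The immediate early genes and the inflammatory genes were divided, as 13 of 29 were higher and 6 lower (15 and 9 adjusted over the list alone) in the former and 9 of 27 were higher and 6 lower (11 and 7 adjusted over the list alone) in the latter. In the interferon-stimulated list 1 of 48 were higher and 9 lower (1 and 12 adjusted over the list alone), at a median of -0.17. The control median was -0.13, and 0 of the 14 control genes passed (limma, 3 at an unadjusted p under 0.05, 0 adjusted over the list alone). Against untreated cells, 23 rose and 4 fell among 34 cAMP and CREB target genes (26 and 4 adjusted over the list alone) and 16 rose and 0 fell among 27 inflammatory cytokine and chemokine genes (18 and 0 adjusted over the list alone) after KDO with 8-Br.

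Measured against the sum of KDO and 8-Br alone, the combination exceeded it for Timp1 by 2.05 ± 0.14 (adjusted p = 0.000282), Il10 by 1.96 ± 0.13 (adjusted p = 0.000282), Il6 by 1.76 ± 0.13 (adjusted p = 0.000339) and Il1a by 1.5 ± 0.14. It fell short for Egr1 (-2.54 ± 0.25), Egr2 (-2.04 ± 0.15) and Btg2 (-2.39 ± 0.17). Dusp2 and Cxcl2 were saturated on 3 and 4 of 4 arrays of the combination, so their departures are not determined. For Tnf the departure was 0.30 and did not pass (adjusted p = 0.742). In the immediate early list 0 of 29 were higher and 12 lower (0 and 19 adjusted over the list alone) than the sum, at a median of -0.73 (adjusted p = 9.04e-35 with the preset correlation and adjusted p = 0.163 with an estimated correlation). Departures passed for 147 higher and 68 lower probes. The split turned between the times, with 1585 higher and 510 lower at 60 min and 204 higher and 518 lower at 120 min. However, the 60 min departures subtract the 8-Br 60 min extract, whose 2781 lower calls count toward higher departures. The control median of the departure was 0.39 at 60 min and -0.20 at 120 min. The turn therefore cannot be read as a difference in how KDO and 8-Br combine over time. The total of 215 became 966 without the first KDO 120 min extract, 848 (175 lower) without the second, 83 without the untreated pair, 77 (36 lower) without the 3 arrays whose labels conflict, 388 without the KDO 120 min array with another series number, 0 with both times taken as replicates (limma, 175 at an unadjusted p under 0.05) and 0 with the dye labels in place of the title order (limma, 672 at an unadjusted p under 0.05). As higher and lower departures they numbered 0 and 1 with the scanner software's processed signals, 3 and 6 with offset 0 and 29 and 54 with median centring. 8-Br added to KDO gave 421 higher and 512 lower (183 at least 2-fold). KDO with 8-Br against untreated cells gave 827 higher and 933 lower (266 at least 2-fold). The 933 calls of the former became 3294 without the first KDO 120 min extract, 1821 without the second, 487 (218 lower) without the untreated pair, 450 (192 lower) without the 3 arrays whose labels conflict, 25 (8 lower) with both times taken as replicates and 48 (3 lower) with the dye labels in place of the title order. Their higher and lower numbers were 155 and 65 with the scanner software's processed signals, 173 and 80 with offset 0 and 307 and 805 with median centring. The 1760 calls of the latter became 3192 without the first KDO 120 min extract, 3197 without the second, 255 (50 lower) with both times taken as replicates and 267 (78 lower) with the dye labels in place of the title order. Split into higher and lower, there were 548 and 373 with the scanner software's processed signals and 561 and 402 with offset 0.

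**Figure D1:**
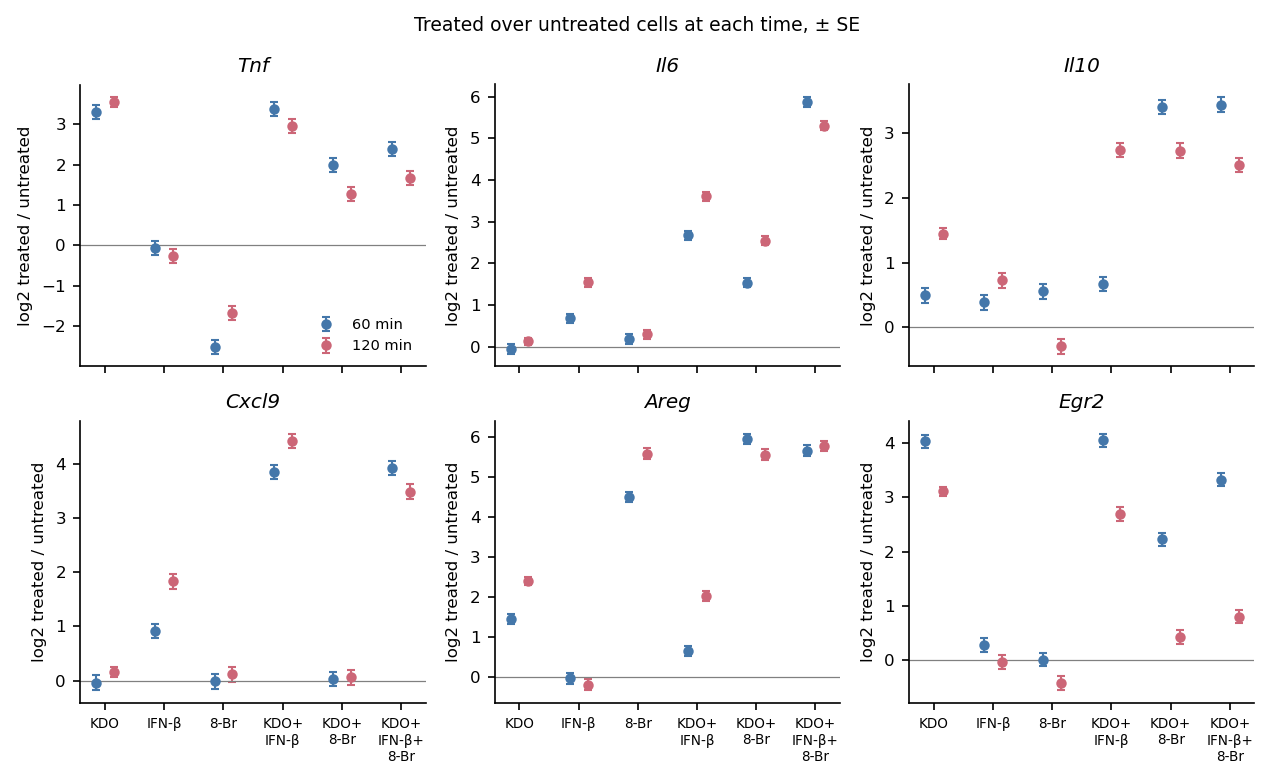
Log2 ratio of treated over untreated (± SE) of Tnf, Il6, Il10, Cxcl9, Areg and Egr2 in the 6 treatments at 60 min (blue) and 120 min (red), 1 extract per point except KDO at 120 min with 2. The mean of both times for Il6 was 0.042 with KDO, 3.14 with KDO and IFN-β, 2.04 with KDO and 8-Br and 5.59 with all 3 ligands.

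With all 3 ligands (n = 2 extracts on 4 arrays), Il6 reached 5.59 ± 0.08 (adjusted p = 2.98e-10) against untreated cells, Areg 5.71 ± 0.09 and Il1b 4.89 ± 0.10, while Tnf was at 2.03 ± 0.12. Compared with KDO and IFN-β, the addition of 8-Br raised Il6 by a further 2.45 ± 0.11 (adjusted p = 2.91e-06), Areg by 4.38 ± 0.13, Nr4a1 by 3.87 ± 0.11, Vegfa by 2.82 ± 0.11 and Procr by 2.68 ± 0.12. Lif, which encodes a cytokine of the interleukin-6 family, and Csf3 were higher by 2.16 ± 0.11 and 2.70 ± 0.15, with second probes at 0.076 and -0.36. Rgs16 (-2.69 ± 0.15), Atf3 (-1.5 ± 0.12), Plk2 (-1.49 ± 0.11), Myc (-1.35 ± 0.13), Egr2 (-1.30 ± 0.13) and Tnf (-1.14 ± 0.17) were lower. Cxcl9 did not pass (-0.44, adjusted p = 0.111). Of the 34 measured cAMP and CREB target genes, 16 were higher, 3 were lower and 15 did not pass the threshold (20 and 5 adjusted over the list alone), at a median of 0.51 (adjusted p = 6.78e-13 with the preset correlation and adjusted p = 0.165 with an estimated correlation). 0 of 48 interferon-stimulated genes were higher and 2 were lower (0 and 4 adjusted over the list alone). In the inflammatory list 9 of 27 were higher and 5 lower (10 and 10 adjusted over the list alone), where the median of -0.018 and the mean of 0.29 differ in sign. Against untreated cells, 47 rose and 0 fell among 48 interferon-stimulated genes (47 and 0 adjusted over the list alone) and 19 rose and 0 fell among 27 inflammatory cytokine and chemokine genes (20 and 0 adjusted over the list alone). In contrast, 0 of the 14 control genes passed (limma, 1 at an unadjusted p under 0.05, 0 adjusted over the list alone). Over all probes the 3 ligands gave 1648 higher and 1410 lower against untreated cells (411 at least 2-fold), and 8-Br added to KDO and IFN-β gave 340 higher and 225 lower (129 at least 2-fold). On both 120 min arrays with all 3 ligands title and dye label conflict. With the dye labels 19 gene values of 8-Br added to KDO and IFN-β reversed, including Il6 (-2.86), Areg, Vegfa, Procr, Lif and Csf3. The camera direction of the cAMP list in this comparison (adjusted p = 0.0714) and of the interferon-stimulated list with all 3 ligands (adjusted p = 3.45e-11) turned to lower. Both arrays then had r = -0.567 and -0.629 with the 60 min extract, which argues against the labels. The 3058 calls became 4883 without the first KDO 120 min extract, 4891 without the second, 619 (195 lower) with both times taken as replicates and 0 with the dye labels in place of the title order (limma, 1543 at an unadjusted p under 0.05). The 565 calls became 2350 (1227 lower) without the first KDO 120 min extract, 2352 (1227 lower) without the second, 285 without the untreated pair, 910 without the KDO 120 min array with another series number, 11 (1 lower) with both times taken as replicates and 204 (190 lower) with the dye labels in place of the title order. By direction, there were 68 and 18 with the scanner software's processed signals, 87 and 25 with offset 0 and 309 and 76 with median centring.

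**Figure D2:**
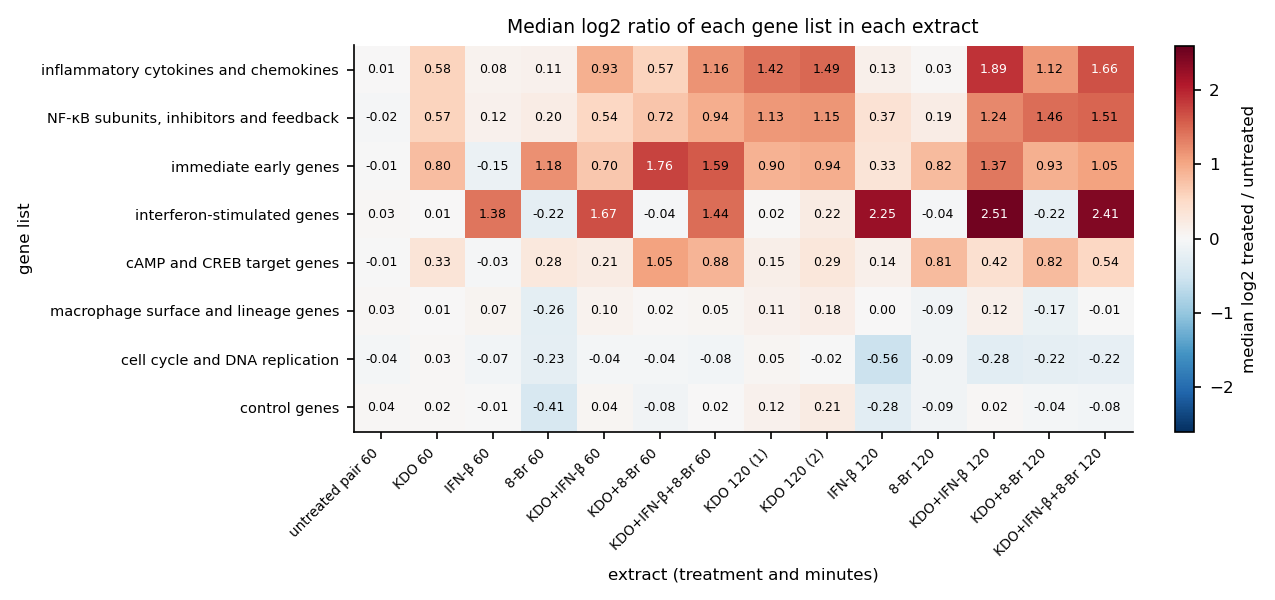
Median log2 ratio of treated over untreated of 8 gene lists (vertical) in each of the 14 extracts (horizontal), written in each cell. The interferon-stimulated genes stood at 1.38 and 2.25 in the 2 IFN-β extracts, and the control genes at -0.41 in the 8-Br 60 min extract and -0.28 in the IFN-β 120 min extract, the 2 lowest of the 14.

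The time points were compared over the mean of the 6 treatments, although the treated 120 min arrays, except 1 of KDO, carried another series number than the treated 60 min arrays. Time and series could therefore not be separated for the other treatments. Il11, which encodes a cytokine of the interleukin-6 family, was higher at 120 min by 1.65 ± 0.06 (adjusted p = 4.52e-06), the AP-1 repressor gene Jdp2 by 1.44 ± 0.07 and Abca1 by 1.40 ± 0.06. Egr2 (-1.22 ± 0.07), the lipid droplet gene Hilpda (-1.31 ± 0.07), the calcineurin inhibitor gene Rcan1 (-1.28 ± 0.08) and Tnfaip3 (-0.97 ± 0.08) were lower. Of the 48 measured interferon-stimulated genes, 31 were higher, 2 were lower and 15 did not pass the threshold (34 and 2 adjusted over the list alone). The list median rose with IFN-β (1.38 to 2.25), KDO and IFN-β (1.67 to 2.51) and all 3 ligands (1.44 to 2.41). In treatments without IFN-β it lay between -0.22 and 0.22. The median difference was 0.31, and 0.23 without the 8-Br 60 min and IFN-β 120 min extracts. Counts in brackets below are adjusted over the list alone. Of the inflammatory genes 13 of 27 were higher and 0 lower (13 and 0). Of the NF-κB genes 16 of 25 were higher and 4 lower (17 and 4). In the cell cycle list 1 of 36 were higher and 9 lower (1 and 11). In the control list 0 of 14 were higher and 2 lower (0 and 2), at a median of 0.10. In all 1606 were higher and 1241 lower at 120 min, 36 of them at least 2-fold. The 2847 calls became 4452 without the first KDO 120 min extract, 5087 without the second and 60 (38 lower) with the dye labels in place of the title order, with a split of 1423 and 2550 with median centring. With the dye labels camera turned the interferon-stimulated (adjusted p = 1.28e-19), inflammatory (adjusted p = 0.00394) and NF-κB (adjusted p = 0.00644) lists to lower at 120 min. Over the 4 treatments other than IFN-β and 8-Br alone 2285 differed. At single times the calls numbered 245 and 3108 with KDO at 60 and 120 min, 263 and 5549 with IFN-β, 4487 and 774 with 8-Br, 604 and 2805 with KDO and IFN-β, 511 and 2297 with KDO and 8-Br, and 978 and 3529 with all 3 ligands. Each single-time total other than KDO at 120 min rests on 1 extract that is assumed to vary like the replicated ones.

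**Figure D3:**
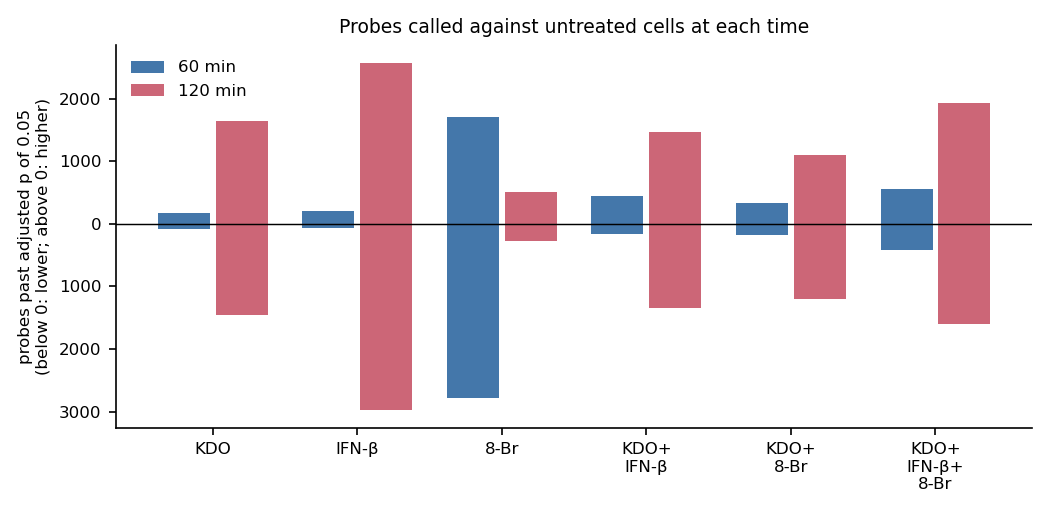
Number of probes past an adjusted p of 0.05, higher (above 0) and lower (below 0) than in untreated cells, for each of the 6 treatments at 60 and 120 min. KDO gave 167 higher and 78 lower at 60 min and 1645 and 1463 at 120 min, IFN-β gave 201 and 62 at 60 min and 2570 and 2979 at 120 min, and 8-Br gave 1706 and 2781 at 60 min and 502 and 272 at 120 min.

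No camera call among the 180 list tests held with an estimated correlation, where the lowest adjusted p was 0.163. That version rests on 2 residual degrees of freedom, so its p-values cannot show that correlation among genes undid the calls. For the NF-κB list with KDO the estimated correlation was -0.0346, below the preset 0.01. Its camera p before adjustment still went from 1.12e-32 to 0.00562. The median, mean and camera direction of a list differed in sign in some tests. These were the cell cycle list with KDO, the protease list with IFN-β, and the MHC, protease and other-cell lists with 8-Br. With combinations against untreated cells they were the other-cell list with KDO and IFN-β, and the macrophage, control and other-cell lists with all 3 ligands. For 8-Br added to KDO they were the negative-regulator, MHC, sterol, stress and protease lists. For 8-Br added to KDO and IFN-β they were the inflammatory, MHC, cell cycle, macrophage and other-cell lists. For IFN-β added to KDO they were the NF-κB, immediate early, cAMP and macrophage lists. The departures added the interferon-stimulated, negative-regulator, MHC, protease and other-cell lists for KDO with 8-Br and the sterol, protease and other-cell lists for KDO with IFN-β, and the time comparison the stress list.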

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

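The tests of the responses to 8-Br and IFN-β, of signal loss along transcripts and of KDO in the untreated scanner files were chosen only after the result was seen, while those of the untreated channels and of differences within value-table pairs were chosen before.

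The effects at 60 and 120 min differed within every treatment, by limma's test of the difference in the same fit, with 1 extract at each time (2 for KDO at 120 min). With KDO 132 probes differed, with IFN-β 4238, with 8-Br 3323, with KDO and IFN-β 907, with KDO and 8-Br 375 and with all 3 ligands 856. The named genes with the largest difference in each direction (120 minus 60 min, log2) were as follows. Gadd45a differed by 1.70 with KDO (adjusted p = 0.00218) from 1.32 at 60 min, and Dusp1 by -1.61 (adjusted p = 0.00147) from 2.92. With IFN-β, Hnrnpa0 differed by 2.98 (adjusted p = 0.00106) from -1.01 at 60 min and Serinc3 by -2.43 (adjusted p = 0.000111) from 0.19. With 8-Br, Abca1 differed by 3.51 (adjusted p = 1.02e-05) from -0.49 and Hilpda by -2.54 (adjusted p = 2.90e-05) from 2.54. With KDO and IFN-β, Il15 differed by 2.16 (adjusted p = 0.000817) from 1.85 and Tnfaip3 by -1.69 (adjusted p = 0.00315) from 3.16. With KDO and 8-Br, Il11 differed by 3.10 (adjusted p = 3.41e-05) from 1.36 and Hilpda by -3.75 (adjusted p = 1.56e-05) from 3.84. With all 3 ligands, Il11 differed by 3.56 (adjusted p = 1.82e-05) from 0.65 and Egr2 by -2.52 (adjusted p = 0.000320) from 3.33. Each lone extract was assumed to vary like the replicated ones, and series numbers differed between times as stated above.

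The high counts of IFN-β and 8-Br rest on 2 extracts that shared a set of falls. At least 2-fold lower in both the 8-Br 60 min and the IFN-β 120 min extract were 597 probes, with medians of -1.69 and -1.32. The paired arrays of these extracts correlated at r = 0.944 and r = 0.838 over all probes. The same probes had medians of -0.051 with 8-Br at 120 min, 0.10 with IFN-β at 60 min, 0.089 with KDO at 60 min, 0.13 with KDO and IFN-β at 60 min, 0.27 and 0.42 in the 2 KDO extracts at 120 min and -0.057 in the untreated pair. With KDO and 8-Br at 120 min the median was -0.51, and over all probes this extract correlated with the 8-Br 60 min extract at r = 0.519. A response wherever 8-Br was given for 60 min would have lowered them with all 3 ligands and with KDO and 8-Br at 60 min, where the medians were 0.0957 (median absolute deviation 0.202) and 0.064. A response wherever IFN-β was given for 120 min would have lowered them with all 3 ligands at 120 min, where the median was -0.121 (median absolute deviation 0.267), and with KDO and IFN-β it was -0.386. A raised untreated channel would have stood at least 1 log2 unit above the other arrays of the same time and dye. Its median difference was 0.109 on the 8-Br arrays and 0.251 on the IFN-β arrays, while the treated channel differed by -1.67 and -1.03. These values argue against a raised untreated channel and against a fall of like size wherever 8-Br was given for 60 min. For IFN-β they argue only against a fall of like size relative to untreated cells. The medians of -0.386 and -0.121 lay below those of the 2 KDO extracts at 120 min (0.27 and 0.42). A smaller lowering by IFN-β is therefore not excluded. Targets of each ligand were raised in the extract that carries its label. The 21 cAMP targets raised by 8-Br at 120 min had a median of 1.83 in the 8-Br 60 min extract with 14 above 0.5, and the 37 interferon-stimulated genes raised at 60 min had a median of 2.73 in the IFN-β 120 min extract with 35 above 0.5. Unequal loss of signal along transcripts stays open, because 56.2% of 160 other probes of the same genes stayed above -0.5 in both extracts, while 69.2% of only 13 comparable probes stayed unchanged for genes raised by KDO. A response that the presence of KDO weakens or delays stays open for both ligands. With KDO and 8-Br the medians were 0.064 and -0.51 at 60 and 120 min, and with KDO and IFN-β -0.386 at 120 min. A difference in culture or RNA of these 2 extracts could also be the source and was not tested. In the value table the columns of the 8-Br extract had medians of -1.75 and 0.44 for these probes and those of the IFN-β extract 0.30 and -0.73, so that paired columns did not repeat each other.

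The value-table columns of the untreated pair carried a treatment signal that no comparison of the report uses. They correlated over probes with the KDO 60 min extract of the scanner files at r = 0.890 and 0.815, and with their own arrays at -0.0445 and -0.156. KDO-treated RNA in the scanner files of the untreated pair is argued against by Tnf, which stood at -0.0184 there and at 3.31 in the KDO 60 min extract. In the value table Tnf is exactly 0 in both columns, but also in 4 treated columns whose own arrays gave 3.04 to 3.27, so that this 0 decides nothing. Whether the columns hold the values of the KDO 60 min arrays stays open. The difference between both columns correlated with the difference between these arrays at an absolute r of 0.137 over 10670 probes, and at up to 0.162 with those of other extracts. This lies below the bound of 0.2 set against it, and below the 0.316 to 0.349 of the 3 pairs of columns that both correlated above 0.7 with their own extract. However, of the 7 pairs whose columns both correlated highest with their own treatment and time 3 also lay under 0.2, the lowest at 0.0450, so that this bound would have excluded pairs with matching labels. Both comparisons with other pairs were added after the value was seen. No biological explanation was tested.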

How the results depend on the processing

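The fits without the 8-Br 60 min and IFN-β 120 min extracts and of the value table by column were chosen only after the result was seen. Values are counts of probes past the threshold for each comparison, the sum over single times (25150 in the report's fit), the number of the 12 comparisons in which camera passed for a list, log2 values of genes and camera adjusted p of lists. A count is listed where it moved by more than 1.5 times, and a gene or list value where its direction reversed. Where no reason is given, the cause was not tested. Of 289 gene values and 180 list tests, Aquantile normalization left 289 and 180 on the same side in the same direction. Gene values in the report reversed under the dye labels, the value table and the fit without the 8-Br 60 min and IFN-β 120 min extracts only.

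Background and scaling changed how many probes passed. With the scanner software's processed signals there were 596 for KDO, 1709 for IFN-β, 2252 for 8-Br, 758 for KDO with IFN-β, 921 for KDO with 8-Br, 1514 for all 3 ligands, 220 for 8-Br added to KDO, 214 for IFN-β added to KDO, 86 for 8-Br added to KDO and IFN-β, 1 for the KDO and 8-Br departure, 0 for the KDO and IFN-β departure (1274 unadjusted), 978 for time and 14848 summed over single times. There 225 of 289 gene values and 175 of 180 list tests kept direction and side of the threshold. The other 64 and 5 no longer passed. With an offset of 0 the counts were 597 for KDO, 1799 for IFN-β, 834 for KDO with IFN-β, 963 for KDO with 8-Br, 1619 for all 3 ligands, 253 for 8-Br added to KDO, 265 for IFN-β added to KDO, 112 for 8-Br added to KDO and IFN-β, 9 for the KDO and 8-Br departure, 0 for the KDO and IFN-β departure (1259 unadjusted), 1196 for time and 15673 summed over single times. There 235 of 289 gene values and 177 of 180 list tests kept direction and side of the threshold. The other 54 and 3 no longer passed. Median centring gave 2810 for KDO with IFN-β, 3134 for IFN-β added to KDO and 83 for the KDO and 8-Br departure, and list counts of 5 for the sterol synthesis and efflux genes and 1 for the markers of other cell types. It reversed interferon-stimulated genes (0.605) and control genes (0.867) for the KDO and IFN-β departure. Under it 281 of 289 gene values kept direction and side of the threshold and 8 no longer passed. Of 180 list tests 150 kept both, 10 no longer passed, 18 newly passed and 2 reversed. Without the dye correction there were 1055 for KDO, 1035 for KDO with IFN-β, 401 for 8-Br added to KDO, 410 for IFN-β added to KDO, 220 for 8-Br added to KDO and IFN-β, 28 for the KDO and 8-Br departure and 7 for the KDO and IFN-β departure, and 259 of 289 gene values kept direction and side of the threshold and 30 no longer passed, and for list tests 179 of 180 kept direction and side of the threshold and 1 newly passed. Testing all non-control probes gave 2 for the sterol synthesis and efflux genes. There 289 of 289 gene values and 179 of 180 list tests kept direction and side of the threshold, and 1 list test newly passed. Requiring signal well above background in both channels on every array gave 3 for the protease, matrix and adhesion genes with fewer probes tested (9821), and 259 of 260 gene values kept direction and side of the threshold and 1 newly passed, and for list tests 171 of 180 kept direction and side of the threshold, 8 no longer passed and 1 newly passed. The signal over background thus limited which probes could be tested, and only 260 of 289 gene values could be compared under the last filter.

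The spread used for the test also changed the totals. With both times of a treatment as replicates, where differences between times enter the spread, there were 194 for KDO, 123 for IFN-β, 152 for 8-Br, 318 for KDO with IFN-β, 255 for KDO with 8-Br, 619 for all 3 ligands, 25 for 8-Br added to KDO, 71 for IFN-β added to KDO, 11 for 8-Br added to KDO and IFN-β, 0 for the KDO and 8-Br departure (175 unadjusted) and 2 for the KDO and IFN-β departure. There 95 of 279 gene values kept direction and side of the threshold and 184 no longer passed. Of 165 list tests 150 kept both, 12 no longer passed and 3 newly passed, and no time comparison exists. No paired analysis was possible because each treated array already sets its extract against untreated RNA and no other numbering pairs the extracts. With the extract as a random block of an array-level fit there were 3306 for KDO, 2812 for KDO with IFN-β, 2885 for KDO with 8-Br, 2444 for 8-Br added to KDO, 2626 for IFN-β added to KDO, 1934 for 8-Br added to KDO and IFN-β, 891 for the KDO and 8-Br departure and 414 for the KDO and IFN-β departure, with 1 for the control genes, and with the slide as block 424 for the KDO and 8-Br departure, with 1 for the control genes. These fits take 28 arrays as samples (16 residual degrees of freedom), so the 2 arrays of 1 extract count as replicates. The block correlation was -0.264 for extract and -0.0378 for slide, and a negative value does not widen the spread for shared extracts. The fits therefore do not check spread between extracts. For the extract block 255 of 259 gene values kept direction and side of the threshold and 4 newly passed. For the slide block 256 kept both, 2 no longer passed and 1 newly passed. For each block 171 of 180 list tests kept both, 4 no longer passed and 5 newly passed. A further limit of 2-fold left 142 for KDO, 184 for IFN-β, 428 for 8-Br, 278 for KDO with IFN-β, 266 for KDO with 8-Br, 411 for all 3 ligands, 183 for 8-Br added to KDO, 177 for IFN-β added to KDO, 129 for 8-Br added to KDO and IFN-β, 69 for the KDO and 8-Br departure, 36 for time and 5681 summed over single times, by its construction. With an estimated correlation camera passed in 0 comparisons for each of 14 lists (limma, lowest adjusted p = 0.163), and markers of other cell types had none in either case. That version decides nothing about correlation among genes, as stated above.

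Leaving out samples changes which samples measure the spread. Without either KDO extract at 120 min in turn, where only the untreated pair measures it and the lone extracts are assumed to vary like that pair, counts ranged over 2456 to 3976 for KDO, 3524 to 3527 for KDO with IFN-β, 3192 to 3197 for KDO with 8-Br, 4883 to 4891 for all 3 ligands, 1821 to 3294 for 8-Br added to KDO, 2153 to 3834 for IFN-β added to KDO, 2350 to 2352 for 8-Br added to KDO and IFN-β, 848 to 966 for the KDO and 8-Br departure, 498 to 889 for the KDO and IFN-β departure and 4452 to 5087 for time. Single times summed to 37174 to 39360, and the sterol list passed in 1 to 2 comparisons. Without the first extract 284 of 289 gene values and 172 of 180 list tests kept direction and side of the threshold. Newly passed were 5 and 4, and 4 list tests no longer passed. Without the second 286 and 175 kept both. Newly passed were 3 and 2, and 3 list tests no longer passed. Without the untreated pair, where only the KDO extracts at 120 min measure the spread, there were 1160 for KDO, 1067 for KDO with IFN-β, 487 for 8-Br added to KDO, 509 for IFN-β added to KDO, 285 for 8-Br added to KDO and IFN-β, 83 for the KDO and 8-Br departure and 23 for the KDO and IFN-β departure, and 269 of 289 gene values kept direction and side of the threshold and 20 no longer passed, and for list tests 177 of 180 kept direction and side of the threshold and 3 newly passed. Taking the KDO 120 min array with another series number as its own extract gave 1103 for KDO, 2047 for IFN-β, 877 for KDO with IFN-β, 965 for KDO with 8-Br, 1733 for all 3 ligands, 380 for 8-Br added to KDO, 380 for IFN-β added to KDO, 207 for 8-Br added to KDO and IFN-β, 48 for the KDO and 8-Br departure, 9 for the KDO and IFN-β departure and 1461 for time, with 2 for the sterol synthesis and efflux genes, and 244 of 280 gene values kept direction and side of the threshold and 36 no longer passed, and for list tests 175 of 180 kept direction and side of the threshold, 1 no longer passed and 4 newly passed. Leaving it out gave 910 for 8-Br added to KDO and IFN-β, 388 for the KDO and 8-Br departure and 87 for the KDO and IFN-β departure, with 2 for the sterol synthesis and efflux genes, and 286 of 288 gene values kept direction and side of the threshold, 1 no longer passed and 1 newly passed, and for list tests 173 of 180 kept direction and side of the threshold, 3 no longer passed and 4 newly passed.

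For the 3 arrays on which title and dye label conflict, leaving them out gave 1144 for KDO, 1067 for KDO with IFN-β, 450 for 8-Br added to KDO, 477 for IFN-β added to KDO, 77 for the KDO and 8-Br departure and 16 for the KDO and IFN-β departure, and 221 of 243 gene values kept direction and side of the threshold and 22 no longer passed, and for list tests 130 of 135 kept direction and side of the threshold, 3 no longer passed and 2 newly passed. It left no sample with all 3 ligands at 120 min, so comparisons with all 3 ligands and of time have no value there. Following the dye labels, which turn these arrays, gave 0 for KDO (728 unadjusted), 629 for IFN-β, 1424 for 8-Br, 293 for KDO with IFN-β, 267 for KDO with 8-Br, 0 for all 3 ligands (1543 unadjusted), 48 for 8-Br added to KDO, 127 for IFN-β added to KDO, 204 for 8-Br added to KDO and IFN-β, 0 for the KDO and 8-Br departure (672 unadjusted), 0 for the KDO and IFN-β departure (562 unadjusted), 60 for time and 7498 summed over single times, with list counts of 5 for the MHC and antigen presentation genes, 2 for the sterol synthesis and efflux genes, 2 for the stress and unfolded protein response genes and 1 for the protease, matrix and adhesion genes. Reversed genes were Abca1 (-1.39), Areg (-1.38), Cd80 (-0.16), Csf3 (-1.26), Dusp1 (-1.55), Fosb (-0.32), Ier3 (-2.85), Il10 (-1.24), Il6 (-2.86), Lif (-1.48), Nfkbie (-1.05), Plaur (-0.93), Procr (-1.0), Sdc1 (-0.61), Slc7a11 (-1.12), Tgm2 (-0.78), Timp1 (-1.37), Traf1 (-2.70) and Vegfa (-0.86) in 8-Br added to KDO and IFN-β. Reversed lists were inflammatory cytokine and chemokine genes (0.844), genes of NF-κB subunits, inhibitors and feedback (0.101), interferon-stimulated genes (3.45e-11), markers of alternative activation (0.335), MHC and antigen presentation genes (0.488), cell cycle and DNA replication genes (0.00256) and protease, matrix and adhesion genes (0.179) for all 3 ligands, and inflammatory cytokine and chemokine genes (0.209) for the KDO and IFN-β departure, and inflammatory cytokine and chemokine genes (0.00394), genes of NF-κB subunits, inhibitors and feedback (0.00644), interferon-stimulated genes (1.28e-19) and markers of alternative activation (0.125) for time, and genes of NF-κB subunits, inhibitors and feedback (7.98e-10), cAMP and CREB target genes (0.0714), markers of alternative activation (0.00248) and protease, matrix and adhesion genes (0.177) for 8-Br added to KDO and IFN-β. There 108 of 289 gene values kept direction and side of the threshold, 162 no longer passed and 19 reversed. Of 180 list tests 135 kept both, 13 no longer passed, 16 newly passed and 16 reversed.

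Without the 8-Br 60 min and IFN-β 120 min extracts there were 263 for IFN-β, 774 for 8-Br, 131 for the KDO and 8-Br departure and 98 for the KDO and IFN-β departure, with 3 for the sterol synthesis and efflux genes and 1 for the control genes. This fit takes 8-Br at 120 min alone and IFN-β at 60 min alone but the other treatments as means of both times, so its departures mix times. Matched in time, 722 passed for KDO and 8-Br at 120 min and 9 for KDO and IFN-β at 60 min. Reversed genes, whose calls came from the extract left out, were Atf4 (0.10), Bub1 (0.012) and Rplp0 (0.074) with 8-Br and Eef1a1 (0.023), Gclm (-0.080), Gusb (0.0069), Mvk (0.088), Rrm2 (0.16), Tbp (0.039) and Txnrd1 (0.13) with IFN-β. Reversed lists were immediate early genes (0.0882), markers of alternative activation (0.827) and control genes (0.595) for the KDO and IFN-β departure. There 251 of 289 gene values kept direction and side of the threshold, 28 no longer passed and 10 reversed. Of 180 list tests 159 kept both, 7 no longer passed, 11 newly passed and 3 reversed.

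In the deposited value table averaged by extract, limma called 0 for KDO (4510 unadjusted), 0 for IFN-β (4604 unadjusted), 0 for 8-Br (3898 unadjusted), 0 for KDO with IFN-β (4733 unadjusted), 0 for KDO with 8-Br (4426 unadjusted), 1753 for all 3 ligands, 0 for 8-Br added to KDO (3368 unadjusted), 0 for IFN-β added to KDO (4164 unadjusted), 0 for 8-Br added to KDO and IFN-β (4321 unadjusted), 0 for the KDO and 8-Br departure (2653 unadjusted), 0 for the KDO and IFN-β departure (4187 unadjusted), 0 for time (5614 unadjusted) and 1408 summed over single times, where 1 residual degree of freedom was left. List counts were 4 for the inflammatory cytokine and chemokine genes, 6 for the genes of NF-κB subunits, inhibitors and feedback, 2 for the negative regulators of TLR and cytokine signalling, 3 for the markers of alternative activation, 0 for the sterol synthesis and efflux genes, 1 for the stress and unfolded protein response genes, 1 for the macrophage surface and lineage genes, 2 for the protease, matrix and adhesion genes and 1 for the control genes. With each column as a sample the calls were 340 for KDO, 256 for IFN-β, 493 for 8-Br, 1089 for KDO with IFN-β, 313 for 8-Br added to KDO, 272 for IFN-β added to KDO, 294 for 8-Br added to KDO and IFN-β, 12 for the KDO and 8-Br departure, 3 for the KDO and IFN-β departure, 1162 for time and 8302 summed over single times, and the list counts 6 for the interferon-stimulated genes, 0 for the sterol synthesis and efflux genes, 1 for the macrophage surface and lineage genes and 0 for the control genes. Reversed genes were the same in both fits, Ccl4 (-0.75), Csf3 (0.054) and Plaur (0.042) in IFN-β added to KDO, Col3a1 (0.026) in 8-Br added to KDO, Csf3 (0.16) in the KDO and IFN-β departure, Eef1a1 (0.26) with IFN-β, Ifit2 (1.14) in 8-Br added to KDO and IFN-β, Krt18 (0.00) with KDO and Rplp0 (0.066) with 8-Br. Reversed lists were genes of NF-κB subunits, inhibitors and feedback (0.908), immediate early genes (0.721) and control genes (0.177) for the KDO and IFN-β departure, and macrophage surface and lineage genes (0.974) for KDO with 8-Br, and control genes (0.319) for IFN-β, and control genes (0.679) for 8-Br in the first, and inflammatory cytokine and chemokine genes (0.686), genes of NF-κB subunits, inhibitors and feedback (0.380), immediate early genes (0.218) and control genes (0.0721) for the KDO and IFN-β departure, and control genes (0.60) for IFN-β, and control genes (0.663) for 8-Br in the second. In the first 6 of 289 gene values kept direction and side of the threshold, 274 no longer passed and 9 reversed. Of its 180 list tests 137 kept both, 34 no longer passed, 3 newly passed and 6 reversed. In the second 135 of 289 gene values kept both, 145 no longer passed and 9 reversed. Of its 180 list tests 149 kept both, 17 no longer passed, 8 newly passed and 6 reversed. For Krt18 the value is 0 and not of the other sign. Several columns of this table do not follow their own arrays.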

Other observations

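In this part the tests of the saturated probes alone and of the 8-Br 60 min extract were chosen only after the result was seen, and those of the saturated share and of compression before.

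Values of Tnf, Il6, Il10, Cxcl9, Myc and Tlr4 in the combinations are set side by side here (log2 ratios over untreated, mean of both times), and these genes were picked for this after their values were seen. Tnf stood at 3.42 with KDO, 3.17 with KDO and IFN-β, 1.63 with KDO and 8-Br and 2.03 with all 3 ligands. Il6 stood at 0.042, 3.14, 2.04 and 5.59 in the same order, and Il10 at 0.97, 1.70, 3.06 and 2.97. Cxcl9 stood at 0.057, 4.14, 0.043 and 3.71, and Myc at 2.41, 0.95, 0.11 and -0.40. Tlr4, at -0.67 with KDO, stood at 0.41 with IFN-β alone and at 0.073 with both, where the difference from KDO was 0.74 (adjusted p = 0.00428).

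KDO and 8-Br together fell short of the sum of the single log2 ratios by at least 1 log2 unit at 33 probes, past the threshold. They exceeded it by as much at 36. Saturation of the scanner would have marked most of the 33, but 9.09% of them, the probes of Dusp2, Cxcl2 and Areg, were saturated in the treated channel of any array with KDO and 8-Br (3, 4 and 1 of 4 arrays), which argues against it for the other 30. For the 3 saturated probes it stays open, because even with the higher array of each extract their departures lay between -4.50 and -0.986 and a saturated value is a lower bound. At 120 min the 33 probes had a median of -1.65 and 27 passed on their own. Those 27 departures therefore do not rest on the 8-Br 60 min extract alone. The 33 were chosen on the mean of both times, so the choice itself lowers their 120 min values. Falls in the 8-Br 60 min extract would instead give positive departures. The 36 positive departures had a median of 0.73 at 120 min, where 17 passed, so for the others that extract stays open. Compression of every large summed change stays open, and its test decides nothing. Probes raised at least 1 log2 unit by KDO and by IFN-β had a median departure of -0.936 (24 probes) and those raised by KDO and by 8-Br -0.976 (46 probes), between the bounds set for the test. Both sets were chosen for high single values and subtract the same KDO values, which lowers the departure by itself, and the former includes saturated probes such as Cxcl10 and Ccl4.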
